A study of Mus musculus with 23 samples.

How the data were processed

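The samples were 23 mouse mammary carcinomas, 11 from vehicle and 12 from abemaciclib animals, each tumour counted as 1 replicate and taken from its title. The titles number tumours and name no animal, so whether any tumours share an animal is not known. All tests treat the 23 tumours as independent. Per the labels' protocols, tumour tissue was snap frozen after the 12th dose, total RNA was extracted with a Macherey Nagel kit, and libraries were made with an Ion AmpliSeq kit and a custom panel that amplifies 1 short stretch of each of 3826 genes. The hours between that dose and freezing are not readable in the labels. The deposited values are raw counts of reads per gene, whole numbers of 0 or more in 1 table of 23 columns, with no normalization. The genome build was mm10, per the submitters' processing notes. The aligner, the counting program and its settings are not given in the sources used here, and neither are the amplicon positions, so the part of each transcript that was read is unknown. Amplicon reads carry no molecular identifiers, so counts include PCR copies, and any limit drawn from counts covers counting error only. 1 gene symbol had been turned into a calendar date by a spreadsheet and was kept as deposited.

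Gene positions came from the GENCODE M21 annotation of GRCm38, the assembly that mm10 names. Of the panel's symbols, 3745 matched directly, 67 through an older symbol and 14 did not match. Positions are 1-based.

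Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups given, which left 2925 genes and set 901 aside. Libraries were scaled with TMM, and differences were tested with glmQLFit and glmQLFTest, two-sided, with Benjamini-Hochberg adjustment at 0.05. The spread between tumours corresponded to a biological coefficient of variation of 32.6%. Group levels are the mean and SD of CPM over tumours, from TMM-scaled totals. List scores average log2 CPM with a prior count of 2. Totals and numbers of detected genes were compared by permutation tests with 100000 resamples. Libraries were checked for copies. Over 253 pairs of tumours the smallest chi-square per degree of freedom was 19.1, so no pair agreed within sampling noise, and Spearman correlations were 0.934 to 0.990.

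Before the data were examined, 33 gene lists were fixed, with 27 of them reaching the minimum of 5 tested members, and the rule for named genes was set. It takes the 12 genes with the smallest p in each direction among those past the adjusted threshold, of which there were 0, up to 3 members with the smallest p from each list, and 14 genes whatever their result, among them Cdk4, Cdk6, Ccnd1, Rb1, Cdkn1a, Cdkn2a, Mki67, Dnmt1, Erbb2, B2m, Cd274, Cd8a and Foxp3. Other genes are said to be chosen after their values were seen. Lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, each against the other tested panel genes, and again with an estimated correlation and with fry. The panel is a selected set of genes, so camera compares lists with that set and not with the transcriptome.

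The fit was tested on simulated counts for 2925 genes drawn from these tumours' means, scaled totals and dispersions. In this simulated comparison of abemaciclib with control, 40 of 67 genes changed 1.5-fold were recovered, 66 of 67 changed 2-fold and 66 of 66 changed 4-fold, with 5 of 2685 unchanged genes called. The changed genes were drawn from outside the fixed lists, so recovery of list members was not tested. In the real comparison Mki67, at a log2 fold change of -1.04, had an adjusted p of 0.150 by edgeR. A count of 0 genes called therefore does not exclude 2-fold changes. A G2/M list shifted by -0.5 was recovered and 0 of 26 other lists were called, but genes were drawn independently of each other, so this does not test how often camera calls lists of correlated genes falsely. In these tumours the estimated correlation was 0.853 for G2/M and 0.634 for E2F targets.

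Alternatives fixed beforehand were DESeq2 size factors, library totals alone, upper-quartile factors, scaling to the housekeeping list, no filter on low counts, a mean count of at least 50, the Wald test of DESeq2 1.42.0, limma-voom with quality weights, the replicate number as a block, robust empirical Bayes, and leaving out each tumour in turn. Added after seeing the data were fits without abemaciclib tumours 3 and 10, without abemaciclib tumour 9 and control tumour 8, and without the Rn7sk amplicon. Alternatives for normalized values, such as other pseudocounts, did not apply, since the values are counts. No tumour was left out of the reported comparison.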

Results

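Gene expression was measured in 23 mammary carcinomas of mice, 11 from animals given vehicle and 12 from animals given abemaciclib, a small-molecule inhibitor of the cyclin-dependent kinases CDK4 and CDK6. The tumours had been induced with doxycycline, the animals were randomized once tumours were established, and the treated animals received 90 mg/kg by gavage each day until tissue was taken after 12 doses. The assay was a targeted amplicon panel, in which 1 short amplicon stands for each of 3826 mouse genes. Libraries held 3044380 to 4492736 counts in control and 2756919 to 4990391 in abemaciclib tumours. The log10 total was 6.59 ± 0.047 (SD, n = 11) and 6.61 ± 0.0655 (SD, n = 12), a difference of 0.018 (permutation test, p = 0.477; this and the other permutation tests were two-sided), and the number of genes with at least 1 count was 3303 ± 37.8 and 3309 ± 42.1 (p = 0.717). Rn7sk, a small nuclear RNA, took 13.0 ± 4.77% of the counts in control and 12.0 ± 3.54% in abemaciclib tumours (p = 0.609). After adjustment over the 4 depth measures compared, each of these p-values was 0.717.

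The comparison of abemaciclib with vehicle asked which transcripts differ in established tumours under CDK4 and CDK6 inhibition. By edgeR no single gene passed the threshold over all genes, while DESeq2's Wald test called 60 and limma-voom with quality weights 127, with 51 called by both. Cell division genes lay lower and antigen presentation, interferon, macrophage and lysosome genes lay higher in the abemaciclib group, as lists under a preset correlation between genes. None of these list calls held with an estimated correlation (adjusted p = 0.0656 to 0.112 with an estimated correlation). Mki67, a marker of dividing cells (chromosome 7, 135689784 to 135716361, mm10), was at 90.1 ± 32.2 CPM (SD, n = 11) in control and 43.7 ± 32.0 CPM (SD, n = 12) in abemaciclib tumours, a log2 fold change of -1.04 (SE 0.340, adjusted p = 0.150 by edgeR), and lay below the control median in 11 of 12 abemaciclib tumours. B2m, the light chain of MHC class I (chromosome 2, 122147686 to 122153083), was at 4712 ± 2615 and 10729 ± 5354 CPM, a log2 fold change of 1.19 (SE 0.295, adjusted p = 0.0709), and lay above the control median in 11 of 12. The smallest adjusted p by edgeR, 0.0574, belonged to Slc11a1, Irx3 and Cdkn2c. Slc11a1, a metal transporter of phagosomes (chromosome 1, 74375195 to 74386062), was at a log2 fold change of 0.91 (SE 0.184). Irx3, a homeobox transcription factor (chromosome 8, 91798525 to 91802067), was at -0.57 (SE 0.118). Cdkn2c, an inhibitor of CDK4 and CDK6 (chromosome 4, 109660876 to 109667189), was at -1.25 (SE 0.260). Slc11a1 and Irx3 were chosen after their values were seen. Slc11a1 was above the control median in 12 of 12 abemaciclib tumours, and Irx3 and Cdkn2c were below it in 12 of 12. Other tests called some of these genes. The adjusted p by DESeq2's Wald test and by limma-voom was 0.00512 and 0.0137 for B2m, and 0.00150 and 0.00709 for Slc11a1. It was 0.00457 and 0.0111 for Irx3, and 0.00178 and 0.0128 for Cdkn2c. Mki67 passed by limma-voom (adjusted p = 0.0111) and not by DESeq2.

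**Figure D1:**
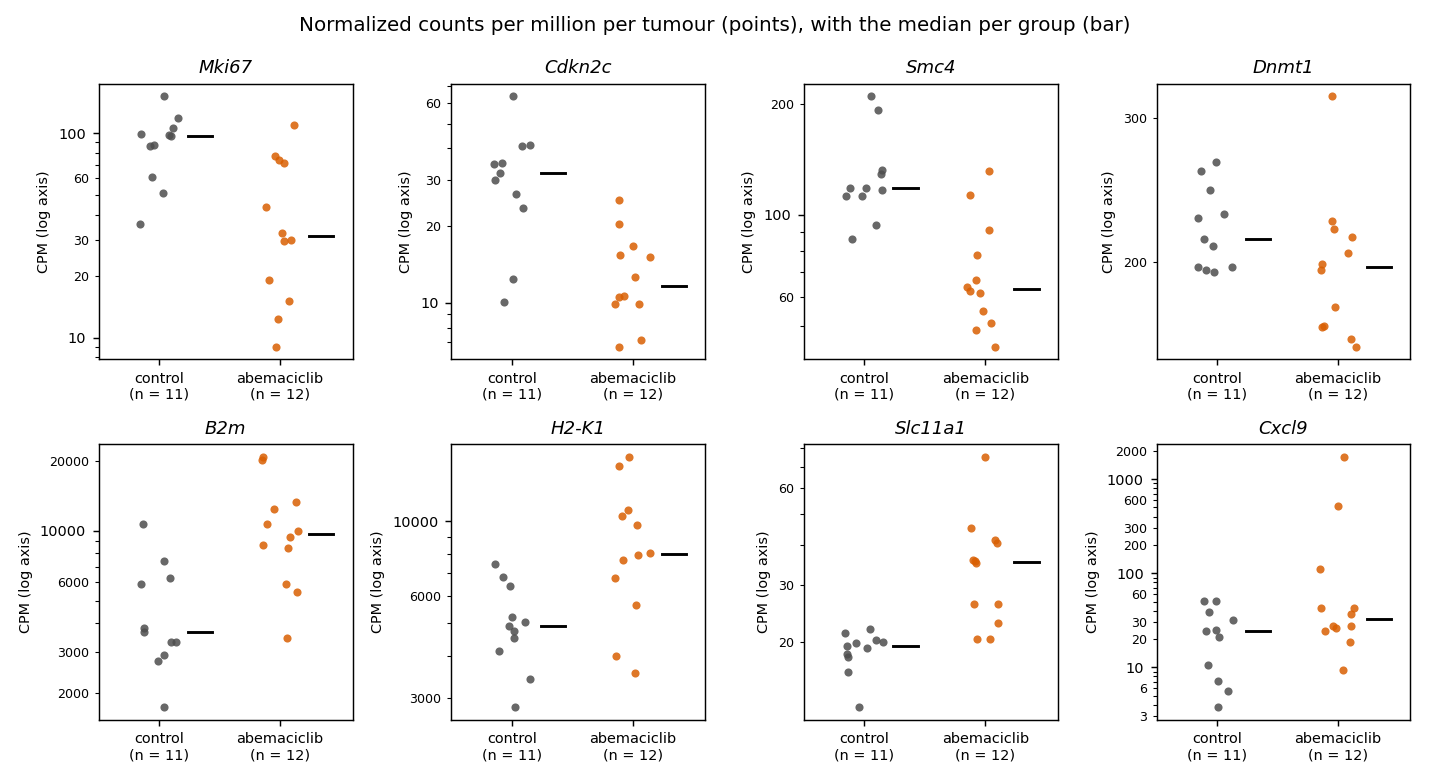
Normalized counts (CPM, scaled to library size) of 8 genes in each tumour, on log axes, with 11 control and 12 abemaciclib tumours as points and the group median as a bar. Mki67 and Cdkn2c had lower medians with abemaciclib and B2m and Slc11a1 higher ones, with overlap between the groups for each of these genes, and 2 abemaciclib tumours stood at 520 and 1726 CPM of Cxcl9.

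By edgeR's quasi-likelihood test, 0 genes were higher and 0 lower with abemaciclib at a Benjamini-Hochberg adjusted p under 0.05 among 2925 genes tested. At an unadjusted p under 0.05 there were 222 higher and 170 lower genes, 392 in all, against 146 for independent genes with no difference, and 6 of 100 splits of the tumours into groups of these sizes gave as many. DESeq2's Wald test called 47 higher and 13 lower genes and limma-voom with quality weights 57 and 70, with 51 genes called by both. The counts depended on single tumours. Leaving out abemaciclib tumour 10 gave 21 higher and 26 lower genes, abemaciclib tumour 2 gave 19 and 11, control tumour 6 gave 5 and 4, and abemaciclib tumour 3 gave 4 and 6. Leaving out control tumour 5 gave 1 and 1, control tumour 1 gave 0 and 2, and abemaciclib tumours 5 or 9 gave 1 and 0. Without abemaciclib tumours 3 and 10, which stood apart on the third principal component and were left out after seeing the data, 32 genes were higher and 61 lower. Without abemaciclib tumour 9 and control tumour 8, also chosen after seeing the data, 1 gene was higher and 1 lower.

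Genes of the mitotic programme fell as a list. All 30 tested members of the G2/M list had negative log2 fold changes, with a median of -1.01. By edgeR, 27 fell when adjusted over the list alone, with 0 of 30 past the threshold over all genes. Limma-voom with quality weights passed members over all genes, among them Smc4 (adjusted p = 0.00709), Bub1b and Cdc25c (0.0111 each). DESeq2's Wald test passed Smc4 (adjusted p = 0.00496) and Bub1b (0.0296) but not Cdc25c. Smc4, a condensin subunit, had a log2 fold change of -0.84 (SE 0.181), Bub1b, a spindle checkpoint kinase, -1.27 (SE 0.373), and Cdc25c, a phosphatase that activates CDK1, -1.38 (SE 0.412). The camera test with a preset correlation gave an adjusted p of 3.21e-31, and the call was lost with an estimated correlation (adjusted p = 0.0891 with an estimated correlation). Of 19 tested E2F targets and DNA replication genes, all 19 had negative values with a median of -0.53, and 12 fell when adjusted over the list alone. Cdc6, which loads replication origins, was at -1.19 (SE 0.326), the kinase Cdc7 at -0.95 (SE 0.281) and the cyclin Ccne2 at -0.96 (SE 0.335). The list's adjusted p was 7.27e-13 by camera, and adjusted p = 0.0891 with an estimated correlation, and its score lay below the control median in 10 of 12 abemaciclib tumours. Dnmt1, the maintenance DNA methyltransferase and a member of this list, was at 221 ± 25.7 CPM in control and 200.5 ± 44.1 CPM in abemaciclib tumours, a log2 fold change of -0.14 (SE 0.103, 95% interval -0.35 to 0.07, adjusted p = 0.585). The 4 tested genes of the DNA methylation machinery had a median of -0.16, too few for a list test.

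The list score, the mean centred log2 CPM over a list's members, was 0.66 ± 0.552 (SD, n = 11) for G2/M in control and -0.61 ± 1.08 (SD, n = 12) in abemaciclib tumours. Of the 12 abemaciclib tumours, 10 lay below the control median and 7 below every control tumour. Abemaciclib tumours 2, 3 and 10 had scores of 0.76, 0.50 and 1.26, inside the control range of -0.38 to 1.74. Markers of luminal mammary epithelium had a median log2 fold change of -0.02 over 13 tested members and a mean of 0.025 (camera adjusted p = 0.946), so that median and mean differed in sign. Their score lay below the control median in 11 of 12 abemaciclib tumours, with means of 0.0068 in control and -0.0062 in abemaciclib tumours.

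**Figure D2:**
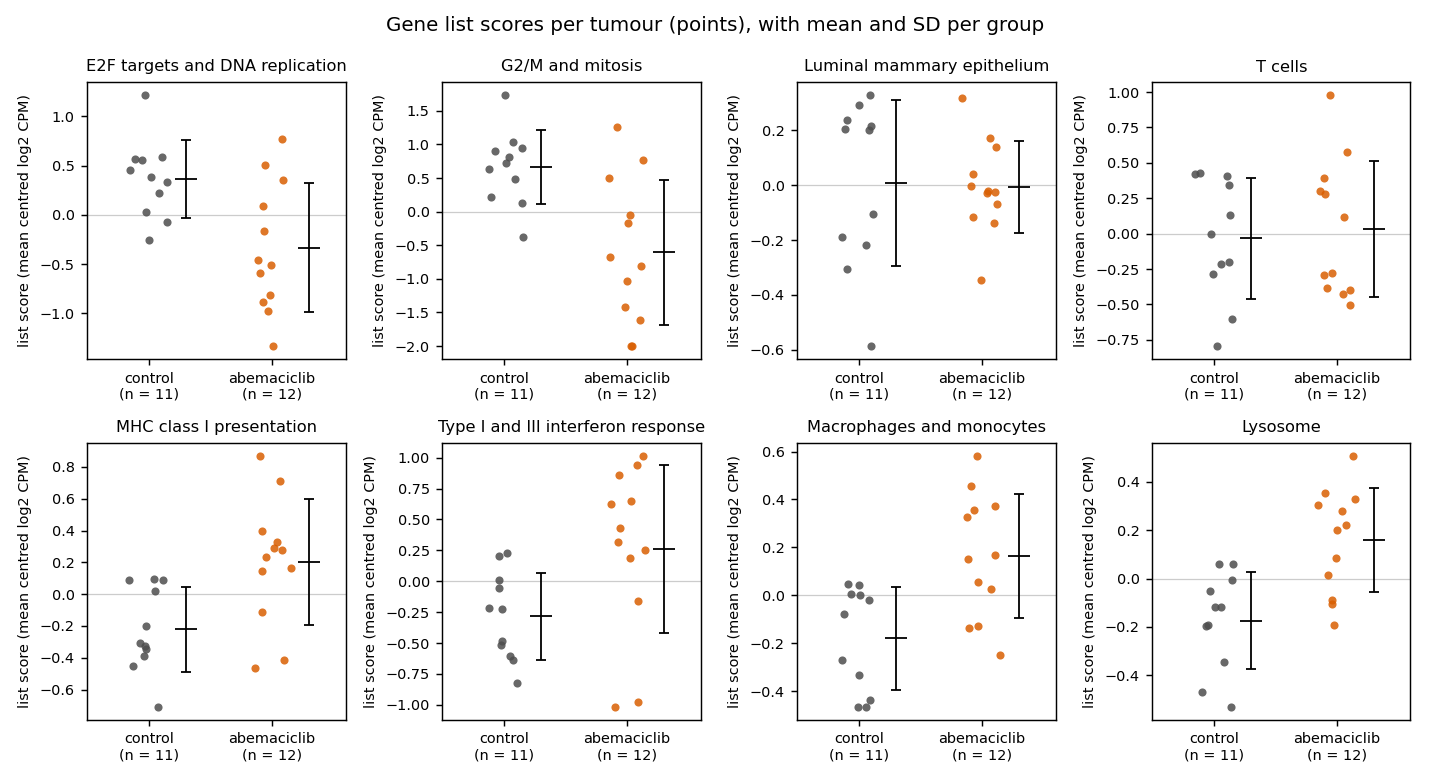
Scores of 8 gene lists in each tumour, as the mean over members of log2 CPM centred on all tumours, with points for 11 control and 12 abemaciclib tumours and the mean and SD beside them. G2/M scores averaged 0.66 in control and -0.61 in abemaciclib tumours, and MHC class I scores -0.22 and 0.20.

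Homologous recombination and mismatch repair genes fell as a list, with 16 of 17 tested members negative, a median of -0.35 and 3 that fell when adjusted over the list alone. These were Rad51c, a recombinase paralogue, at -0.92 (SE 0.209), Rpa3, a subunit of the single-strand binding complex, at -0.70 (SE 0.211), and Parp1, a sensor of DNA breaks, at -0.31 (SE 0.107). Camera gave an adjusted p of 6.50e-08, and adjusted p = 0.0891 with an estimated correlation, and the score lay below the control median in 10 of 12 abemaciclib tumours. That score followed the G2/M score within each group, with Pearson's r of 0.925 in control and 0.943 in abemaciclib tumours. A lower level of these genes is therefore not separate from the lower G2/M genes. The CDK-RB list had 20 of 25 members negative, a median of -0.20 and a camera adjusted p of 4.54e-06 (adjusted p = 0.0891 with an estimated correlation), and 1 member, Cdkn2c, fell when adjusted over the list alone. Of these 25 genes, 5 are also E2F list members. The drug's targets and their partners did not pass the test. Cdk4 was at -0.14 (SE 0.222), Cdk6 at 0.06 (SE 0.206), Ccnd1 at -0.16 (SE 0.321), Rb1 at 0.04 (SE 0.131), Cdkn1a at -0.03 (SE 0.217), Cdkn2a at -0.18 (SE 0.139) and Cdkn1b at -0.43 (SE 0.150). Ccnd2, another D-type cyclin, chosen after its values were seen, was at 0.91 (SE 0.352), above the control median in 11 of 12 abemaciclib tumours, with an adjusted p of 0.0558 over the list alone. Over all genes these 8 had adjusted p from 0.185 for Cdkn1b to 0.973 for Cdkn1a. The signs of Cdk6 and Rb1 turned with scaling to library totals or to housekeeping genes. The p53 targets had 7 positive and 7 negative members and a median of 0.026 (adjusted p = 0.946).

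MHC class I genes rose as a list. Of 9 tested members, 5 rose when adjusted over the list alone and 7 were positive, with a median of 0.36. H2-K1, a class I heavy chain, was at 5044 ± 1415 CPM in control and 8719 ± 3723 CPM in abemaciclib tumours, a log2 fold change of 0.79 (SE 0.217, adjusted p = 0.0912), and H2-D1 had one of 0.83 (SE 0.230, adjusted p = 0.0956). Reads of these 2 genes are uncertain, since class I heavy chains are near copies of each other. The others, B2m aside, were the proteasome genes Psmb8 at 0.69 (SE 0.217) and Psme2 at 0.21 (SE 0.0879), both chosen after their values were seen. The other 4 members had values from -0.014 to 0.36. Camera gave the list an adjusted p of 4.70e-05, and adjusted p = 0.112 with an estimated correlation. The list score was above all control tumours in 9 of 12 abemaciclib tumours. All 5 tested MHC class II pathway genes were positive with a median of 0.44, and 4 rose when adjusted over the list alone, Ctss at 0.59 (SE 0.158), Lgmn at 0.40 (SE 0.118), H2-DMa at 0.52 (SE 0.199) and Cd74, named after its value was seen, at 0.44 (SE 0.178). The adjusted p was 4.65e-05 by camera and adjusted p = 0.0891 with an estimated correlation, with scores above the control median in 10 of 12 abemaciclib tumours.

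The 2 lists of interferon-response genes were also higher under the preset correlation. In the type I and III list all 10 tested members were positive with a median of 0.62, and 9 rose when adjusted over the list alone, among them the antiviral gene Oas1a at 0.75 (SE 0.247) and Herc6 at 0.85 (SE 0.286). Camera gave an adjusted p of 1.93e-07, and adjusted p = 0.105 with an estimated correlation, with scores above the control median in 10 of 12 abemaciclib tumours. Of the abemaciclib tumours, 8 scored above every control tumour and 2 below every control tumour. The latter were abemaciclib tumours 2 and 9, at -1.02 and -0.98 against a control minimum of -0.83. In the type II list all 12 were positive with a median of 0.57 and 6 rose when adjusted over the list alone, including the adhesion molecules Vcam1 at 0.84 (SE 0.224) and Icam1 at 0.49 (SE 0.137). Its adjusted p was 3.19e-05, and adjusted p = 0.0891 with an estimated correlation. Cxcl9, an interferon-induced chemokine of the same list, was at 3.16 (SE 0.834), a value set by abemaciclib tumours 3 and 10 at 520 and 1726 CPM against 9.41 to 111 CPM in the other 10 and 3.75 to 50.8 CPM in control tumours, and it was at 1.73 without abemaciclib tumour 10 and 0.58 without both. Without both, the type II list had a median of 0.31 and an adjusted p of 0.0219, in a range of 2.27e-06 to 0.0891 over its alternatives. Nucleic acid sensing genes had a median of 0.29 over 11 members, 8 of them positive and 0 past the threshold over the list alone, with Irf7 at 1.17 (SE 0.419), Tlr7 at 0.63 (SE 0.228) and Eif2ak2 at 0.35 (SE 0.132). That list's adjusted p was 0.00395 and adjusted p = 0.102 with an estimated correlation, and 3 of its members are also in the type I and III list. Cd274, which encodes PD-L1, was at 0.64 (SE 0.357, adjusted p = 0.449), on 5 to 98 counts per tumour, or 0.38 without abemaciclib tumour 10.

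Macrophage markers rose as a list, with 12 of 13 tested members positive and a median of 0.45. Of these, 5 rose when adjusted over the list alone, the scavenger receptor Msr1 at 0.73 (SE 0.168), the Fc receptor Fcgr3 at 0.69 (SE 0.188), the complement gene C1qa at 0.47 (SE 0.133) and, named after their values were seen, the chemokine Ccl2 at 1.02 (SE 0.391), or 0.40 without abemaciclib tumour 10, and the receptor Csf1r at 0.45 (SE 0.182). Ccr2, a receptor of circulating monocytes, also named after its value was seen, fell by 0.72 (SE 0.277) with an adjusted p of 0.0384 over the list alone. The list's adjusted p was 3.19e-05 by camera, and adjusted p = 0.0656 with an estimated correlation, with scores above the control median in 9 of 12 abemaciclib tumours. Dendritic cell markers had a median of 0.58 over 6 members, of which Ly75 at 0.79 (SE 0.186) and Itgax at 0.65 (SE 0.179) rose when adjusted over the list alone (camera adjusted p = 8.47e-04, and adjusted p = 0.0656 with an estimated correlation). Lysosome genes were positive in 12 of 12 members with a median of 0.34, and 8 rose when adjusted over the list alone, including Hexa, a subunit of hexosaminidase, at 0.69 (SE 0.158), the protease Ctsl at 0.41 (SE 0.101) and Gaa, acid alpha-glucosidase, at 0.37 (SE 0.109). Their adjusted p was 2.82e-08, and adjusted p = 0.0656 with an estimated correlation, with scores above the control median in 11 of 12 abemaciclib tumours.

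T cell markers did not pass. They had a median of 0.31 and a mean of 0.095 over 9 tested members of 20 on the panel (camera adjusted p = 0.545). Cytotoxic and natural killer genes had a median of -0.30 over 5 tested members of 12 on the panel (camera adjusted p = 0.422). The rest were set aside by the filter on low counts, so these values cover only the genes above it. Cd8a, the co-receptor of cytotoxic T cells, was at 3.28 ± 2.59 CPM in control and 3.31 ± 2.91 CPM in abemaciclib tumours, with 1 to 28 and 2 to 47 counts per tumour and a log2 fold change of 0.04 (SE 0.480, adjusted p = 0.979), and its sign turned with scaling to library totals or to housekeeping genes. Foxp3, the transcription factor of regulatory T cells, was left out by the filter on low counts, at 0 to 24 counts in control and 1 to 16 in abemaciclib tumours. With no filter it was at -0.24 (p = 0.577, adjusted p = 0.853 by edgeR). Of 12 regulatory T cell genes on the panel, 5 were tested, with a median of -0.13, a mean of 0.09 and an adjusted p of 0.795, so that median and mean differed in sign. Entpd1, an ectonucleotidase also made by other leukocytes and endothelium, rose by 0.46 (SE 0.139) when adjusted over that list alone. The 4 tested checkpoint genes had a median of 0.59, too few for a list test. Lag3, an inhibitory receptor of lymphocytes, was at 0.85 (SE 0.311), with an adjusted p of 0.0439 over these 4 genes and 0.206 over all genes by edgeR. Adjustment over a list alone does not correct for the number of lists.

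**Figure D3:**
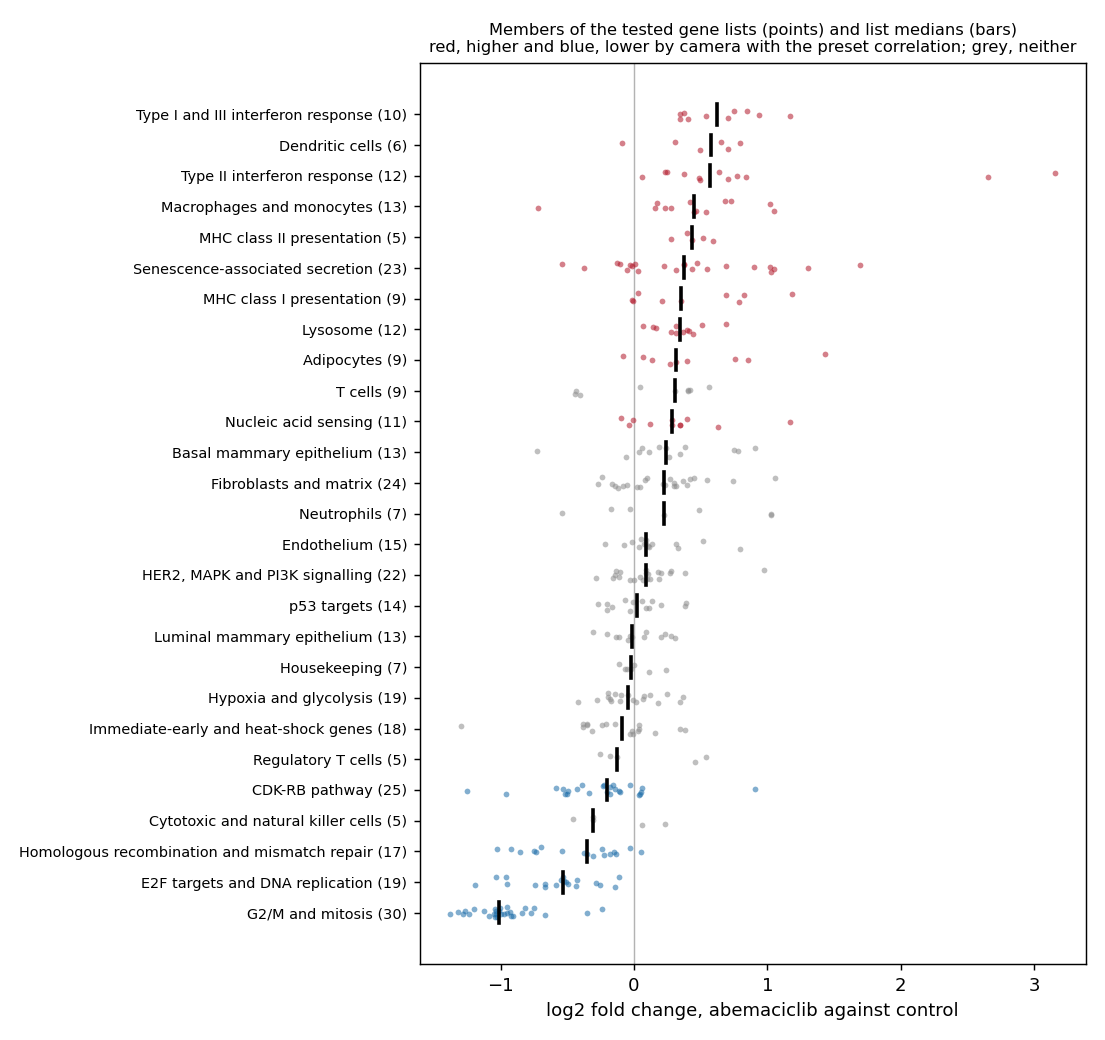
Log2 fold change of abemaciclib against control for each tested member of 27 gene lists, with the list median as a bar and the number of tested members in brackets. By camera with the preset correlation 10 lists were higher and 4 lower, and 0 and 0 with an estimated correlation, with medians from -1.01 for G2/M to 0.62 for the type I and III interferon response.

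The senescence-associated secretory list and the adipocyte list rose under the preset correlation only. The secretory list had a median of 0.38 over 23 members, 16 of them positive, with an adjusted p of 0.00482, and adjusted p = 0.178 with an estimated correlation. The matrix metalloproteases Mmp3 at 1.69 (SE 0.375) and Mmp13 at 1.31 (SE 0.415) and the chemokine Cxcl2 at 1.03 (SE 0.266) rose when adjusted over the list alone. Without abemaciclib tumours 3 and 10 the secretory list lost its call (adjusted p = 0.136, in a range of 1.03e-04 to 0.178 over its alternatives). The adipocyte list had a median of 0.31 over 9 members and an adjusted p of 0.00494, and adjusted p = 0.234 with an estimated correlation. Its 1 member that rose when adjusted over the list alone was Cd36, a fatty acid transporter, at 1.43 (SE 0.432), and Scd1, a fatty acid desaturase, was at 0.85 (SE 0.384), or 0.55 without abemaciclib tumour 5. Both lists were lost with fry, at adjusted p of 0.0793 and 0.104.

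Neutrophil genes had a median of 0.23 and an adjusted p of 0.0844, which fell under the threshold when any of control tumours 3, 5, 8 or 10 or abemaciclib tumours 4, 5, 7 or 11 was left out (0.0327 to 0.0483, in a range of 0.0173 to 0.328 over its alternatives). Its member Cxcl2 also rose when adjusted over that list alone. Fibroblast and matrix genes had a median of 0.23 (adjusted p = 0.397, and 0.0183 without abemaciclib tumour 12, in a range of 0.0183 to 0.940 over its alternatives) and endothelial genes one of 0.09 (adjusted p = 0.259, and 0.0373 without control tumour 11, in a range of 0.0373 to 0.758). Basal epithelial markers had a median of 0.24 (adjusted p = 0.330), hypoxia and glycolysis genes -0.046 (adjusted p = 0.481), and signalling genes of the HER2, MAPK and PI3K pathways 0.09 (adjusted p = 0.387), with Erbb2 itself at -0.12 (SE 0.146). Immediate-early and heat-shock genes had a median of -0.09 (adjusted p = 0.138, and 0.0426 without abemaciclib tumour 8, in a range of 0.0426 to 0.442), and Nr4a1, a nuclear receptor induced early after stimulation, fell by 1.30 (SE 0.351) when adjusted over that list alone. The 7 housekeeping genes had a median of -0.024 and a mean of 0.014 (adjusted p = 0.964), which differ in sign. Both tested platelet genes, the chemokines Ppbp at 1.48 (SE 0.367) and Pf4 at 0.70 (SE 0.286), rose when adjusted over their list of 2 alone. Over all genes their adjusted p was 0.0651 and 0.248 by edgeR. Ppbp had few counts, 1 to 12 in control and 4 to 44 in abemaciclib tumours. B and plasma cell, mast cell and skeletal muscle genes had 2, 1 and 2 tested members, with medians of 0.41, 0.11 and 0.96 and none past the threshold over the list alone.

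Of the 27 lists tested, 10 were higher and 4 lower with the preset correlation of 0.01, 0 and 0 with an estimated correlation, and 8 and 4 by fry, which tests a list's own genes without comparing them with other genes. With the preset correlation, 94 of 99 other splits of the same tumours also called 1 or more lists. Scaling to library totals alone moved the median of all genes by -0.13, and left 11 lists higher and 4 lower, with 99 genes higher and 422 lower at an unadjusted p under 0.05.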

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

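Fits without abemaciclib tumours 3 and 10, without abemaciclib tumour 9 and control tumour 8, and without the Rn7sk amplicon were chosen after seeing the data. The count of 0 higher and 0 lower genes by edgeR held with DESeq2 size factors, upper-quartile factors, housekeeping scaling, no filter, a mean count of at least 50, robust empirical Bayes and without Rn7sk. It became 0 and 1 with library totals, 47 and 13 by DESeq2's Wald test, 57 and 70 by limma-voom with quality weights, 32 and 61 without abemaciclib tumours 3 and 10, and 1 and 1 without abemaciclib tumour 9 and control tumour 8. Leaving out each tumour in turn gave 0 to 21 higher and 0 to 26 lower genes. The 10 higher and 4 lower lists became 0 and 0 with an estimated correlation. Other settings gave 8 to 11 higher and 4 lower lists, and leaving out each tumour 10 to 11 and 4 to 5. The cause was not tested.

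The labels do not say whether tumours that share a replicate number form a pair. The correlation of same-numbered deviations ran from -0.43 to 0.45 over 11 such couples, and 2 of 11 control tumours correlated best with their own number. These values show no clear pairing and do not exclude one. With the replicate block 0 genes were higher and 0 lower, 354 had an unadjusted p under 0.05, and 11 lists were higher and 4 lower, with fibroblast genes added (adjusted p = 0.0298).

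In the alternatives run, directions turned for these results, each far from the threshold. Cdk6 was at -0.040 with library totals, -0.10 with housekeeping scaling, -0.042 by voom, -0.12 without abemaciclib tumours 3 and 10 and -0.033 without abemaciclib tumour 9 and control tumour 8, and -0.037 to 0.13 leaving out each tumour. Cd8a was at -0.029, -0.12, -0.22, -0.47 and -0.031 in the same order, at -0.0035 with the replicate block and -0.28 to 0.26 leaving out each tumour. Rb1 was at -0.077 with library totals and -0.023 with housekeeping scaling, and -0.025 to 0.094 leaving out each tumour. Cdkn1a was at 0.0084 without abemaciclib tumour 9 and control tumour 8 and -0.16 to 0.027 leaving out each tumour. Krt14, at 0.91 with all tumours, was at -0.36 by voom and -0.71 without abemaciclib tumours 3 and 10. Lists turned at these adjusted p: housekeeping 0.882 with library totals, 0.984 with housekeeping scaling, 0.970 with no filter and 0.583 without abemaciclib tumour 9 and control tumour 8; p53 targets 0.951 with the replicate block and 0.569 without abemaciclib tumours 3 and 10; regulatory T cells 0.970 with no filter; T cells and basal epithelium 0.873 each without abemaciclib tumours 3 and 10; fibroblasts 0.759 and luminal epithelium 0.583 without abemaciclib tumour 9 and control tumour 8. Leaving out each tumour, the adjusted p ran from 0.717 to 0.998 for housekeeping, 0.647 to 0.991 for p53 targets, 0.647 to 0.986 for luminal epithelium and 0.401 to 0.995 for T cells. The neutrophil list passed with library totals, housekeeping scaling and no filter (0.0173 to 0.0268). Named genes kept direction and side 754 times and crossed the threshold 89 times in the fits that left out no single tumour, and 1458 and 57 times when 1 tumour was left out, with the direction kept at each crossing. Low counts limited Foxp3, Cd8a, Ppbp and Cd274, and other named genes as well. Among these, Cxcl2 had 4 to 14 counts in control and 5 to 30 in abemaciclib tumours. Lag3 had 4 to 26 and 7 to 67, Cdc25c 7 to 57 and 1 to 38, Cdc6 17 to 78 and 3 to 56, and Ccr2 13 to 52 and 6 to 32, in the same order.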

Other observations

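Of the tests below, those of the splits for the count of genes past the threshold and for the G2/M median, of luminal dilution, of macrophages, of the difference in spread, the choice of tumours left out, and the relations between list scores other than that of MHC class I within abemaciclib tumours were chosen after the values were seen. Within each group, tumours with lower G2/M scores had higher scores of the adipocyte list, which includes Cd36 and Scd1, and of the lysosome list. Among 12 abemaciclib tumours, Pearson's r between the G2/M and adipocyte scores was -0.858 and Spearman's rho -0.860 (permutation p = 5.50e-04 and 6.00e-04, adjusted 0.00357 and 0.00422), and r was -0.800 without the 2 tumours farthest from the median G2/M score. Among 11 control tumours r was -0.842 and rho -0.764 (permutation p = 0.00135 and 0.00855, adjusted 0.00702 and 0.0296), and r was -0.865 without the 2 farthest. For the lysosome list r was -0.808 and rho -0.818 within abemaciclib tumours (permutation p = 0.00175 and 0.00145, adjusted 0.00758 and 0.00838), and -0.705 and -0.745 within control tumours (permutation p = 0.0124 and 0.0120, adjusted 0.0405 and 0.0367), with r of -0.644 and -0.604 without the 2 farthest. The luminal score also ran against the G2/M score in control tumours, with r of -0.752 and rho of -0.700 (permutation p = 0.00610 and 0.0210, adjusted 0.0234 and 0.0576; r = -0.514 without the 2 farthest), and in abemaciclib tumours r was -0.556 and rho -0.441 (permutation p = 0.0582 and 0.160, adjusted 0.119 and 0.260; r = -0.719 without the 2 farthest). In all, 52 relations of the G2/M score were computed, and those described are not all that passed the correction. The closest were with the E2F, CDK-RB and homologous recombination lists, which were also lower with abemaciclib. In that order, r was 0.987, 0.930 and 0.925 in control tumours and 0.987, 0.954 and 0.943 in abemaciclib tumours (permutation test, adjusted p = 5.20e-04 to 0.00186). These lists varied together with G2/M within each group, so their lower values are not separate findings. The p53 targets followed the G2/M score, with r of 0.843 in control and 0.807 in abemaciclib tumours (permutation test, adjusted p = 0.00702 and 0.00758). In abemaciclib tumours r was 0.739 for immediate-early and heat-shock genes and 0.749 for hypoxia genes (permutation test, adjusted p = 0.0234 each). For hypoxia genes rho did not pass (0.538, adjusted p = 0.156). The secretory list followed the G2/M score in abemaciclib tumours, with r of 0.904 and rho of 0.874 (permutation p = 2.00e-04 and 6.50e-04, adjusted 0.00173 and 0.00422; r = 0.870 without the 2 farthest), while in control tumours r was 0.097 and rho -0.027 (permutation p = 0.779 and 0.946, adjusted 0.844 and 0.946; r = -0.180 without the 2 farthest). Whether the groups differ in this relation was not tested.

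Abemaciclib tumours 3 and 10 stood apart from the other tumours in Krt14, Cst6 and Cxcl9, of which Krt14 and Cst6 were chosen after their values were seen. Krt14, a keratin of basal and squamous cells, was at 9147 and 6110 CPM in them, against 83.6 to 1679 CPM in the other 10 abemaciclib tumours and 247 to 3016 CPM in control tumours. Cst6, a cystatin of stratified epithelium, was at 202 and 270 CPM, against at most 35.9 CPM in the other abemaciclib tumours and 26.0 CPM in control tumours. The same tumours held the highest Cxcl9 of all 23. Hoxb8, a homeobox gene also chosen after its values were seen, stood at 137 CPM and 533 counts in control tumour 11, against at most 20 counts in each of the other 22 tumours, and the fitted log2 fold change of -2.95 became -0.30 without that tumour. No explanation was tested for these values.

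Lower G2/M genes with abemaciclib was the pattern with the median farthest from 0 among the 27 tested lists. Of the 100 splits of the 23 tumours into groups of 11 and 12, drawn with the real one included, 2 gave a median of any of the tested lists as far from 0 as the real 1.01 of G2/M, with 1.05 as the highest of the others, a share under the 0.05 set for excluding chance. After every library was thinned to the smallest total the median was -1.02. Totals differed little between the groups beforehand (log10 difference 0.018), so thinning could hardly have moved the median and adds no evidence against depth. The difference between the G2/M and luminal scores was -1.25, abemaciclib minus control (permutation p = 0.00856). The G2/M score alone differed by -1.27 and the luminal score by -0.013, so this value nearly restates the G2/M difference. It shows only that luminal markers as a list did not fall by as much as G2/M genes. The luminal score ran against G2/M within control tumours, so it may not gauge the share of epithelial cells. Fewer epithelial cells therefore stay open as a cause. A larger share of fat cells, as far as the adipocyte list gauges it, also stays open as a part of the cause. The adipocyte score was higher by 0.45 with abemaciclib and ran against G2/M within both groups. A lower rate of division under CDK4 and CDK6 inhibition may account for the lower G2/M genes. That is a hypothesis on the data it was found in, and processing or collection differences that the labels do not give stay open.

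Higher MHC class I genes might reflect more macrophages or the 2 tumours set apart. The class I list score was higher with abemaciclib by 0.42, an excess of 0.0797 over the difference in the macrophage list score (permutation p = 0.406), so more macrophages stay open as a cause. Without abemaciclib tumours 3 and 10 the list median was 0.35 (adjusted p = 0.00175 by camera with the preset correlation, in a range of 2.61e-06 to 0.112 over its alternatives). Their class I scores were 0.23 and 0.40, against a mean of 0.20 over the abemaciclib tumours. They were thus not far apart in class I genes, and leaving them out was a weak test. It shows only that the higher list did not rest on those tumours. Other leukocytes and reads shared among class I heavy chains stay open, as does a higher level per tumour cell, which bulk tissue cannot separate.

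G2/M scores spread more widely in abemaciclib than in control tumours, with a ratio of mean absolute deviations of 2.21. Thinning to the smallest total left the ratio at 2.19. Totals differed little between the groups (log10 difference 0.018), so thinning could hardly have changed the ratio and adds no evidence against depth. The permutation p of the ratio was 0.0302, and 0.405 after adjustment over the 27 lists. A wider spread therefore cannot be told apart from chance with groups of 11 and 12. Tumours that differ in their response could give such a spread, as a hypothesis that these data leave open.

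Whether abemaciclib tumours with lower G2/M scores carry higher MHC class I scores was set as a hypothesis before that relation was computed. Within the 12 abemaciclib tumours Spearman's rho was -0.23 (permutation p = 0.469, adjusted 0.610) and Pearson's r -0.353 (permutation p = 0.261, adjusted 0.376; r = -0.361 without the 2 farthest), so the relation did not pass. The bound set beforehand against the hypothesis, a permutation p of 0.05 or more, was met but had been set wrongly, since a missed p in 12 tumours does not exclude a negative relation. Within the 11 control tumours r was -0.640 and rho -0.691 (permutation p = 0.0317 and 0.0224, adjusted 0.0801 and 0.0583; r = -0.885 without the 2 farthest), which failed the correction. Related lists passed it within control tumours by rank and not by Pearson's r. For type I and III interferon genes rho was -0.791 and r -0.623 (permutation p = 0.00460 and 0.0362, adjusted 0.0217 and 0.0822; r = -0.808 without the 2 farthest), and for nucleic acid sensing genes rho was -0.736 and r -0.641 (permutation p = 0.0118 and 0.0323, adjusted 0.0367 and 0.0801; r = -0.884 without the 2 farthest). Within abemaciclib tumours neither passed, with rho of -0.252 and -0.531 (permutation p = 0.432 and 0.0781, adjusted 0.605 and 0.156) and r of -0.327 and -0.553 (permutation p = 0.303 and 0.0593, adjusted 0.415 and 0.119; r = -0.453 and -0.581 without the 2 farthest). Whether the groups differ in these relations was not tested.

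Other splits of the tumours also bear on the counts. With 0 genes past the threshold, all 100 splits gave as many by construction, which says nothing about chance. Of the other splits 3 called any gene, with 53 as the highest, and whether that split follows a structure of the tumours was not tested. At an unadjusted p under 0.05, 6 of 100 splits gave at least the real 392 genes, the highest of the others 729, so chance is not excluded for this count. For the 10 higher lists, 3 of 100 splits called as many in 1 direction, with 11 as the highest of the others, a share under the 0.05 set for excluding chance. This holds for camera with the preset correlation, by which 94 of the 99 other splits called 1 or more lists, and with an estimated correlation 0 lists were higher. For the 4 lower lists, 63 of 100 did as many, with 11 as the highest, so chance is not excluded for their number.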
